A study of Drosophila melanogaster with 7 samples.

How the data were processed

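Chromatin immunoprecipitation followed by sequencing (ChIP-Seq) was applied to Drosophila melanogaster S2 cells, a cultured line of embryonic origin. Antibodies against 5 proteins (WOC, ROW, Z4, Dsk2 and HP1c) gave 1 library each, and 2 input libraries (chromatin without immunoprecipitation) completed the 7 samples. Per the labels, 1 input served WOC, ROW and Z4 and the other served Dsk2 and HP1c. The Z4 antibody was raised in guinea pig and the other 4 in rabbit, per the labels.

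The deposited files hold, for each of the 5 immunoprecipitations, a list of called regions with a chromosome, a start and an end. They carry no score, height, fold enrichment, p-value or read number, so the sequencing depth is unknown and region width took the place of a score in every ranking, as had been set before the data were examined. Per the series' design text, regions were called against input. Per the submitters' processing notes, CASAVA 1.8, FastQC 0.9.3 and Bowtie 0.12.5 were used with the dm3 genome build. The peak caller, its threshold and the treatment of duplicate reads are not given in the sources used here. Because each protein had 1 library, regions were called per library and no replicate was available.

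Positions are printed as deposited, in dm3. Some regions start and end at the same position (50 for HP1c, 53 for Dsk2, 61 for WOC, 200 for ROW and 120 for Z4), which is possible only if both ends belong to the region. Widths were therefore computed as end minus start plus 1. Whether the first base of a chromosome is numbered 0 or 1 is not stated, so a printed position could be off by 1 bp. The smallest distance between neighbouring regions was 301 bp in each of the 5 lists. How closer calls were treated before deposit is not given in the sources used here. A region list of this kind records where the signal passed a threshold, not how strong it was. A protein with a stronger or deeper library may have more or wider regions, which could not be checked here.

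Sample groups were taken from the labels. Regions of 2 lists were called overlapping when they shared at least 1 bp. The overlap was compared with 10000 circular rotations of the first list, with a separate random offset on each chromosome arm, in a one-sided permutation test. Arm ends were set to the outermost positions of any list, and p-values were adjusted by the Benjamini-Hochberg method over the 10 pairs. Partners of HP1c were compared with exact McNemar tests (two-sided, adjusted over 6 contrasts). The 5 lists were merged into non-redundant regions, and the number with all 5 proteins was compared with 1000 independent rotations. Widths of shared and unshared regions were compared by permutation of the difference of medians (two-sided, 100000 permutations). Spearman correlations of widths were computed across shared regions, which are not independent replicates. Shares of regions are given with exact (Clopper-Pearson) 95% confidence intervals, which cover the counting of regions only.

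Further comparisons were chosen after the data had been seen. These included the Mantel-Haenszel odds ratios within strata of the other 3 lists, two-sided Fisher exact tests of arm shares between lists (adjusted over 70 tests), overlap within set distances, and width differences with regions counted as shared when their midpoint lay inside the partner. Regions of at least 50 bp and end-exclusive intervals were alternatives chosen then as well, as were the 5 large arms alone for the partner contrasts and the merged regions. Coverage of region midpoints by other lists was tabulated in 50 bp steps to 3000 bp, with exact McNemar tests at 0 and 400 bp (two-sided, adjusted over 40 tests) and 1000 bootstrap resamples. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0, statsmodels 0.14.6 and matplotlib 3.10.9.

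The overlap test was tested on simulated data with the numbers and widths of the HP1c and Dsk2 lists. With partners planted at 50% of 2711 regions, 50.9% were found to overlap, and with none planted 1.85% overlapped. Of 100 unrelated simulated pairs, 3 had a rotation p of 0.05 or less. The simulated lists were matched to the deposited ones in number and width of regions, not in their clustering along the arms. The false-positive rate for the deposited lists, which hold closely spaced regions, therefore cannot be read from these pairs.

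The rule for named regions was fixed before the data were examined. It takes the 10 regions with all 5 proteins that have the best mean width rank, the 3 widest regions of each protein that overlap no other list, and the 5 widest HP1c regions with and without a Dsk2 region. The same rule asked for genes, and gene lists had been fixed. The annotation at hand is of a later genome release than dm3, and coordinates were not converted between builds. Regions were therefore not assigned to genes. Planned comparisons of transcription start sites, bound genes, gene lists, divergent promoters and promoter motifs are not analysed here. Alternatives covered the overlap rule, the width of the regions kept, list length, the rotation scheme, the arms used and the reading of the interval ends.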

Results

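The study mapped 5 chromatin proteins in Drosophila S2 cells and asked how Dsk2 relates to HP1c binding at transcription start sites. HP1c is a euchromatic member of the heterochromatin protein 1 family. WOC and ROW are zinc-finger proteins known as its partners, Dsk2 is a ubiquitin-binding protein of the ubiquilin family, and Z4 is a zinc-finger protein of polytene interbands. Each protein was represented by 1 library and 1 list of called regions. The tests below compare these lists, not repeated immunoprecipitations. The rotation tests keep the spacing of regions within a list, while the other tests and the intervals treat regions as if they were independent. The depth of the libraries is unknown.

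The ROW and Z4 lists were the longest and held the widest regions, and the HP1c list was the shortest. HP1c had 2711 regions with a median width of 121 bp, covering 0.471 Mb. Dsk2 had 4748 regions (median 216 bp, 1.32 Mb covered) and WOC had 5849 (median 205 bp, 1.48 Mb covered). Z4 had 7491 regions (median 352 bp, 3.24 Mb covered) and ROW had 8999 (median 245 bp, 4.40 Mb covered). Regions over 2 kb numbered 367 for ROW and 79 for Z4, but 9 for Dsk2 and 1 each for WOC and HP1c. The widest single region was a ROW region of 18231 bp on 2R, from 6970003 to 6988233, which overlapped WOC, Dsk2 and Z4 regions and no HP1c region. Narrow calls were frequent in every list, and 29.0% of HP1c and 15.7% of Z4 regions were under 50 bp.

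The first comparison asked which proteins occupied the HP1c regions. Dsk2 was found at 62.0% of HP1c regions (1681 of 2711, exact 95% confidence interval 60.15 to 63.8%). WOC was found at 57.7% (55.8 to 59.6%), Z4 at 48.1% (46.2 to 50.04%) and ROW at 28.0% (26.4 to 29.8%). Rotated lists gave 1.75% for Dsk2, 2.02% for WOC, 3.72% for Z4 and 4.90% for ROW. The observed shares were therefore 35.4, 28.6, 12.9 and 5.72 times the rotated ones. All 4 had an adjusted permutation p of 1e-04, the smallest that 10000 rotations can give. Rotation does not account for a common preference of chromatin proteins for open sites. When only as many of the widest regions were kept in each list as HP1c has, all 4 shares of HP1c regions were lower. They were 53.9% for Dsk2, 47.25% for WOC, 29.1% for Z4 and 21.4% for ROW.

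**Figure D1:**
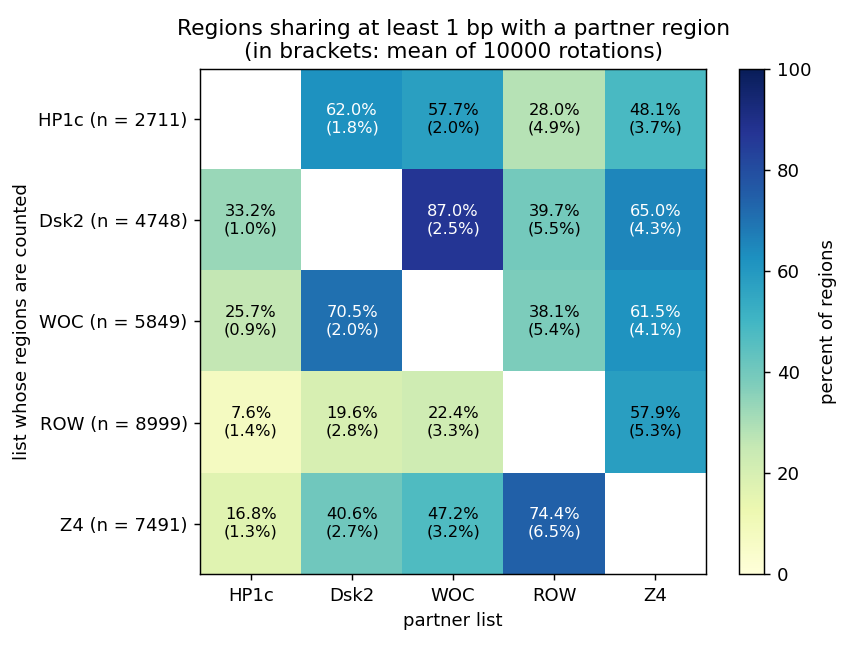
Percent of the regions of each list (rows) that share at least 1 bp with a region of another list (columns), with the mean share under rotation in brackets. The highest share is that of Dsk2 regions with a WOC region (87.0%), and the lowest is that of ROW regions with an HP1c region (7.61%).

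By shared bases, HP1c regions carried Dsk2 more often than any other protein, and ROW least often. With the 50% widest regions of each list, the difference between ROW and Z4 was -0.664 points and did not pass (adjusted p = 0.626, exact McNemar test). Dsk2 exceeded WOC by 4.32 percentage points, since 185 HP1c regions had Dsk2 without WOC and 68 had WOC without Dsk2 (exact McNemar test, adjusted p = 1.10e-13). Dsk2 exceeded Z4 by 13.9 points (adjusted p = 5.06e-44, exact McNemar test) and ROW by 34.0 points (adjusted p = 9.98e-179, exact McNemar test). WOC exceeded ROW by 29.7 points. With equal-length lists Dsk2 exceeded Z4 by 24.8 points and WOC by 6.64 points, and with midpoints within 250 bp it exceeded WOC by 2.77 points. The comparison depended on the distance allowed. Within 500 bp, a ROW region lay near 72.3% of HP1c regions, a Dsk2 region near 70.5%, a WOC region near 70.5% and a Z4 region near 67.1%. The corresponding rotated shares were 10.5%, 5.29%, 6.36% and 8.905%. HP1c and Dsk2 were called against one input and the other 3 proteins against another. In the contrasts of Dsk2 with WOC, ROW or Z4 the input and the partner therefore cannot be told apart, while those among WOC, ROW and Z4 are within 1 input.

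The positions of the partners around HP1c regions differed. Dsk2 regions covered 56.5% of HP1c midpoints and 12.7% of positions 400 bp to the left of them. WOC coverage fell from 51.7% to 12.3% over this distance, and Z4 coverage from 39.3% to 20.2%. ROW showed the opposite order, covering 21.5% of HP1c midpoints, 31.9% of positions 400 bp to the left and 32.6% of positions 400 bp to the right. It covered 13.35% of positions 3000 bp away. The ratio of centre to flank was 0.666 for ROW (95% bootstrap interval 0.624 to 0.709). On the left, 505 midpoints had ROW at the flank alone and 222 at the centre alone (exact McNemar test, adjusted p = 4.13e-26). ROW coverage was also lower at Dsk2 midpoints (26.2%) than 400 bp to the left (31.2%, adjusted p = 2.81e-11, exact McNemar test). At WOC midpoints ROW coverage was 27.4%, against 28.4% 400 bp to the left, and this difference did not pass the test (adjusted p = 0.12, exact McNemar test). The bootstrap interval of the ratio of centre to flank at WOC midpoints was 0.927 to 0.9988. At Z4 midpoints ROW was higher at the centre, with 48.2% against 33.3%. At ROW midpoints WOC coverage was 8.73%, against 11.8% 400 bp to the left (adjusted p = 7.06e-12, exact McNemar test). Dsk2 (7.37% against 10.7%) and HP1c (1.87% against 3.57%) were also lower at ROW midpoints, while Z4 was higher (36.5% against 20.9%). HP1c regions with and without Dsk2 both had less ROW at the centre, with 28.4% against 36.9% to the left in the first set and 10.2% against 23.8% in the second.

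**Figure D2:**
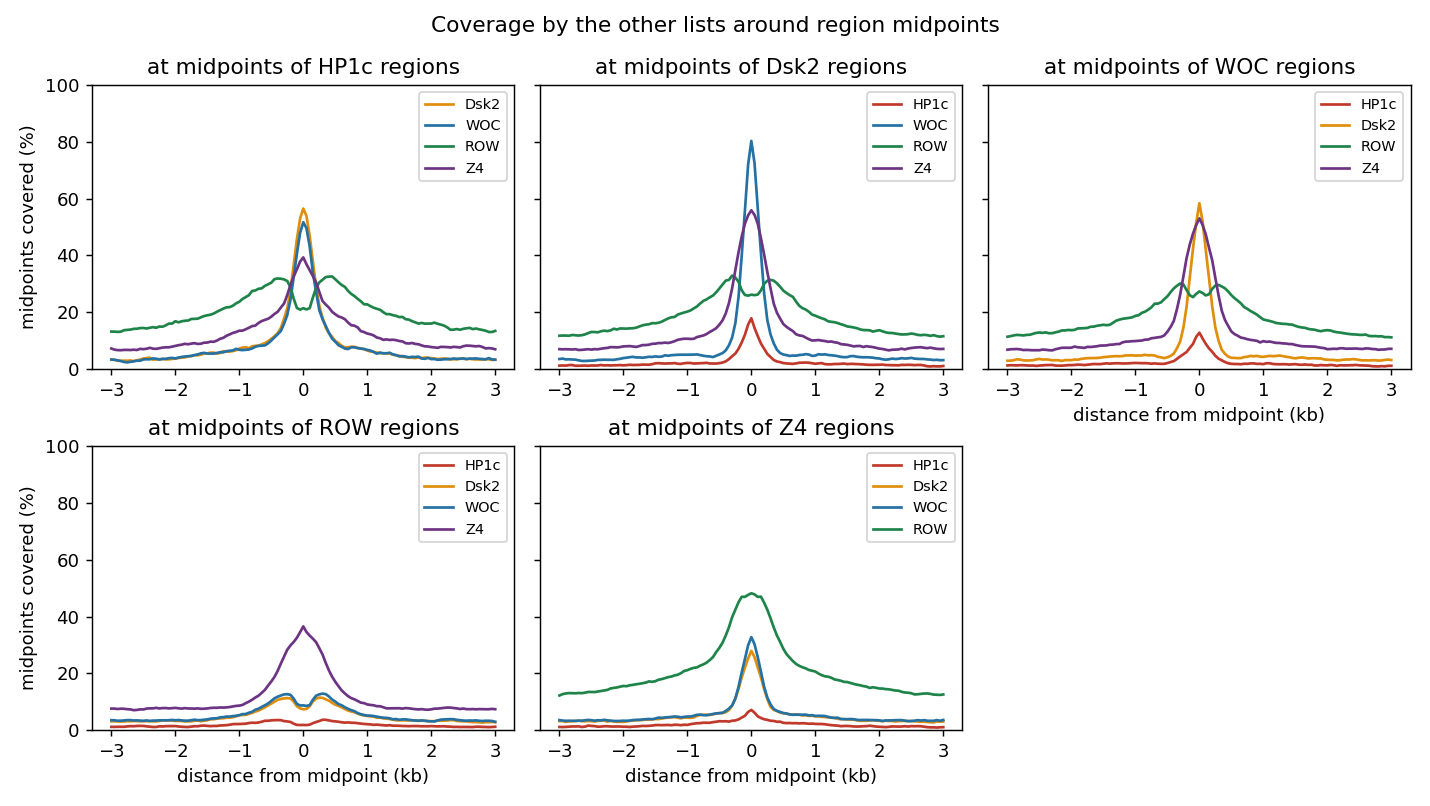
Percent of region midpoints covered by regions of each other list (y axis) against the distance from the midpoint in kb (x axis), with 1 panel per list that gives the midpoints and 1 line per covering list. ROW coverage dips at HP1c midpoints (21.5%) and is higher 400 bp away (31.9% and 32.6%), while Dsk2, WOC and Z4 coverage is highest at the centre.

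Across the 10 pairs, the shares of overlapping regions were highest for Dsk2 with WOC and for Z4 with ROW. Of the Dsk2 regions, 87.0% overlapped a WOC region, against 2.501% under rotation, and 70.5% of WOC regions overlapped a Dsk2 region. Of the Z4 regions, 74.4% overlapped a ROW region (6.51% under rotation), and 57.9% of ROW regions overlapped a Z4 region. Z4 was also present at 65.0% of Dsk2 and 61.5% of WOC regions. All 10 pairs had an adjusted permutation p of 1e-04. Relative to rotation, Z4 with ROW (11.4 times) lay below Dsk2 with WOC (34.8 times) and below HP1c with Dsk2, WOC and Z4, Dsk2 with Z4, and WOC with Z4. Counting only midpoints within 250 bp of each other lowered the share of Z4 regions with ROW to 47.9%, below that of HP1c regions with Dsk2 (56.5%) and of Dsk2 regions with Z4 (56.4%), and left that of Dsk2 regions with WOC at 87.55%.

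Odds ratios within strata of the other 3 lists separated these pairs further. Merged regions with none of those 3 lists were left out, which kept 6804 of 13044 for ROW-Z4. The odds ratios therefore hold only where at least 1 of the other lists had a region. The Dsk2-WOC odds ratio was 88.6 (95% confidence interval 73.9 to 106) and crossed the 2 inputs. It was 20.9 for ROW-Z4 (18.1 to 24.2) and 11.25 for HP1c-Dsk2 (8.80 to 14.4), both within an input. The other pairs within an input were WOC-Z4, at 6.07 (5.09 to 7.24), and WOC-ROW, at 1.51 (1.29 to 1.76). Across the inputs it was 2.68 for Dsk2-Z4 (2.305 to 3.12), 2.26 for HP1c-WOC (1.84 to 2.78) and 1.75 for HP1c-Z4 (1.496 to 2.05). For Dsk2-ROW it was 1.44 (1.24 to 1.67) and for HP1c-ROW 1.26 (1.09 to 1.46). With every region set to 200 bp around its midpoint, the odds ratio was 71.8 for Dsk2-WOC, 6.62 for HP1c-Dsk2 and 5.04 for ROW-Z4. With that setting the interval for HP1c-ROW included 1 (0.927 to 1.19), as did that for Dsk2-ROW (0.795 to 1.02).

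Merging the 5 lists gave 13044 regions. The single most frequent kind was ROW alone, with 3437 regions, followed by ROW with Z4 (1861 regions) and by the 4 proteins Dsk2, WOC, ROW and Z4 without HP1c (1299 regions). All 5 proteins were present in 921 merged regions (7.06%), against a mean of 0.242 and a maximum of 3 under rotation (permutation p = 0.001, the smallest that 1000 rotations can give). Merging joins overlapping regions in a chain, so the 5 proteins need not lie at 1 common site. Of the HP1c regions, 539 (19.9%) each overlapped regions of all 4 other lists. Median merged width rose from 95 bp with 1 list to 424.5 bp with 2 lists and 1160 bp with all 5, and wider merged regions have more room for several lists. Setting every region to 200 bp around its midpoint left 339 regions with all 5.

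**Figure D3:**
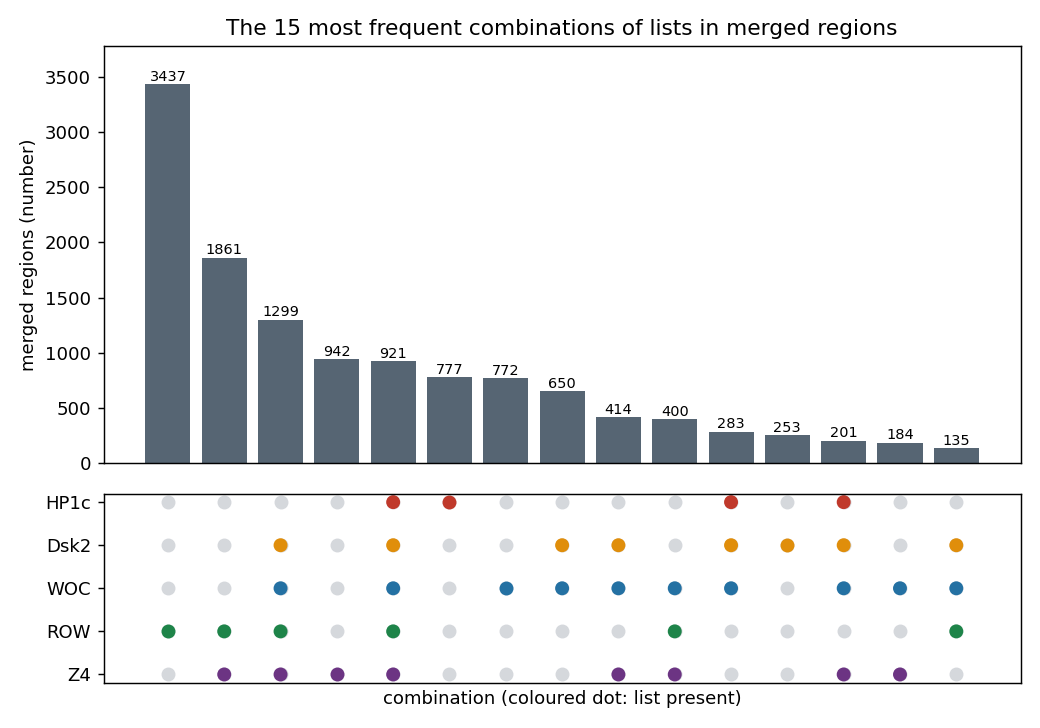
Number of merged regions (y axis) for the 15 most frequent combinations of lists, which the coloured dots below each bar name. ROW alone is the most frequent kind (3437 regions), and 921 regions hold all 5 proteins.

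Among the regions with all 5 proteins, the one with the best mean width rank lay on 3R from 19157162 to 19173142. It held the widest HP1c region of the data (2444 bp, 19159260 to 19161703) and the widest Dsk2 region (4229 bp, 19157572 to 19161800). The second widest ROW region (12602 bp) began at 19160541 in the same place and extended to 19173142. The second in this ranking lay on 2L from 13071378 to 13076705, with an HP1c region of 795 bp and a ROW region of 5328 bp. The third lay on X from 7594193 to 7605031 and held 8 HP1c, 8 Dsk2 and 9 WOC regions beside 2 ROW and 8 Z4 regions. The fourth lay on 2R from 7082884 to 7094260 and held the second widest Dsk2 region (3604 bp). Of the other 6, 2 lay on 3R, 3 on 3L and 1 on 2L, including 3R from 25596350 to 25609776 with a ROW region of 11792 bp and a Z4 region of 7125 bp.

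**Figure D4:**
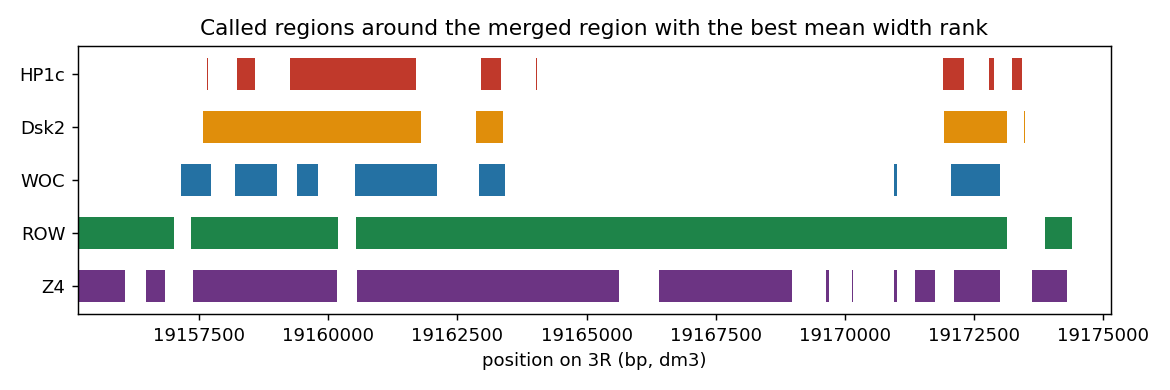
Called regions of the 5 lists (bars, to scale) along 3R in dm3 coordinates around the merged region from 19157162 to 19173142, with 2 kb on each side. HP1c, Dsk2 and WOC regions lie mostly towards both ends, while a ROW region of 12602 bp spans from 19160541 to 19173142.

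HP1c regions without any of the other 4 proteins numbered 777 (28.7%, exact interval 27.0 to 30.4%). By comparison, 253 Dsk2 regions (5.33%), 772 WOC regions (13.2%), 942 Z4 regions (12.6%) and 3437 ROW regions (38.2%) overlapped no other list. The widest HP1c regions of this kind were 818 bp on 3R (27538935 to 27539752), 805 bp on X (19047517 to 19048321) and 676 bp on 2R (5842568 to 5843243). The nearest region of another list was 190, 451 and 1762 bp away from them. The 5 widest HP1c regions with Dsk2 each overlapped all 4 partners. They lay on 3R (2 regions), 3L (2 regions) and 2L. Of the 5 widest without Dsk2, the widest (909 bp on 2R, 7339416 to 7340324) overlapped ROW and Z4, and the other 4 overlapped no list. The widest regions found in 1 list alone for the other proteins were 399 bp for Dsk2 (3R, 25593074 to 25593472), 383 bp for WOC (3L, 3384663 to 3385045), 2487 bp for ROW (2R, 2766420 to 2768906) and 855 bp for Z4 (2L, 22179000 to 22179854).

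Shared regions were wider than unshared ones in 19 of the 20 ordered pairs of lists by the permutation test of medians. Dsk2 regions with WOC had a median of 249 bp, against 33 bp for those without (adjusted p = 1.11e-05, permutation test). WOC regions with Dsk2 had a median of 279 bp, against 52 bp without. HP1c regions had medians of 175 bp with ROW and 105 bp without, and of 139 bp with Dsk2 and 103 bp without, and with Z4 the difference did not pass the test (128 against 119 bp, adjusted p = 0.237, permutation test). A wide region overlaps a partner more easily. When only regions whose midpoint lay inside the partner counted as shared, 15 of the 20 pairs still had wider shared regions by the test, among them Dsk2 with WOC (197 bp) and HP1c with ROW (22 bp, adjusted p = 0.00868, permutation test). This rule reduced the HP1c difference with Dsk2 to 12 bp (adjusted p = 0.0982, permutation test), left -6 bp for WOC (adjusted p = 0.418, permutation test) and gave -38 bp for Z4 (adjusted p = 1.43e-05, permutation test). By the same rule, Z4 regions with HP1c were narrower than those without (-65 bp, adjusted p = 6.67e-05, permutation test), as were Z4 regions with ROW (-21 bp, adjusted p = 0.0111, permutation test). Width ranks at shared regions were correlated between Dsk2 and WOC (Spearman rho 0.719 across 4131 regions), and less between HP1c and Dsk2 (rho 0.2985 across 1681). For Z4 with ROW rho was 0.00968 across 5573 regions (adjusted p = 0.471, permutation test). Negative correlations that passed were those of HP1c with Z4 (rho -0.129, adjusted p = 1.67e-05, permutation test) and of Dsk2 with ROW (rho -0.097, adjusted p = 7.14e-05, permutation test).

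Chromosome 4, the small heterochromatin-rich autosome, held few HP1c regions. HP1c had 10 regions there (0.369% of its list, exact interval 0.177 to 0.677%), Dsk2 52 (1.095%), WOC 54 (0.923%), Z4 66 (0.881%) and ROW 67 (0.745%). Relative to the 5 large arms, HP1c regions per Mb on chromosome 4 were 0.368 times as dense (interval 0.176 to 0.677), and ROW regions 0.742 times (0.575 to 0.943). The ratio was 0.885 for Z4 (0.6835 to 1.13), 0.9275 for WOC (0.696 to 1.21) and 1.11 for Dsk2 (0.825 to 1.45). The HP1c share was below that of Dsk2 (adjusted p = 0.0067, Fisher exact test), WOC (adjusted p = 0.0282, Fisher exact test) and Z4 (adjusted p = 0.0325, Fisher exact test). Its difference from ROW did not pass (adjusted p = 0.153, Fisher exact test). With equal-length lists the difference from Z4 did not pass either (adjusted p = 0.326, Fisher exact test).

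The X chromosome held a larger share of the Dsk2 and WOC lists than of the ROW and Z4 lists. It took 18.9% of Dsk2 and 19.1% of WOC regions, against 15.7% of ROW and 16.4% of Z4 regions. The odds ratio was 1.27 for WOC over ROW (adjusted p = 5.07e-06, Fisher exact test) and 1.19 for Dsk2 over Z4 (adjusted p = 0.00405, Fisher exact test). HP1c, with 17.5% of its regions on X, did not differ from any of the other 4 lists by this test (lowest adjusted p = 0.113, Fisher exact test, against ROW). With equal-length lists HP1c exceeded ROW (12.9%, adjusted p = 1.11e-04, Fisher exact test) and Z4 (12.4%, adjusted p = 1.19e-05, Fisher exact test). That setting compares all HP1c regions with only the widest regions of the other lists. The X share was also lower among the widest Dsk2 (16.75%) and WOC (15.9%) regions than in their full lists. Among the 5 large arms, all 5 lists were densest on 2R, from 25.9 regions per Mb for HP1c to 89.2 for ROW. ROW (63.1 per Mb) and Z4 (54.7 per Mb) were least dense on X.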

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

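Region numbers per arm and equal-length lists had been planned, while the Fisher exact tests between lists on chromosome 4 and the coverage around midpoints were chosen after the lists had been seen. The tests of long ROW regions and of equal-length lists on chromosome 4 were set down before their results were known, and the other tests in this part afterwards, as was the share of the ROW length in narrow regions.

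The share of HP1c regions on chromosome 4 differed from that of 3 other lists by a test of the difference, with an odds ratio of 0.334 against Dsk2, 0.397 against WOC and 0.417 against Z4. A shorter list that keeps the widest regions is argued against for Dsk2 and WOC. The same number of their widest regions each had 1.11% on chromosome 4 (exact interval 0.748 to 1.58%), above the HP1c interval of 0.177 to 0.677%. It is not argued against for ROW (0.516%, 0.283 to 0.865%) or Z4 (0.738%, 0.451 to 1.14%). Width stood in for strength here, so a shorter list that keeps the strongest regions cannot be judged. An effect of the input library or of mapping on chromosome 4 that thins HP1c and Dsk2 to the same degree is argued against as well. Dsk2, called against the same input, was 1.11 times as dense there as on the large arms (interval 0.825 to 1.45). Whether either affected the HP1c calls alone, or Dsk2 to a lesser degree, cannot be told. The difference from ROW did not pass the test, and that from Z4 did not with equal-length lists. The depth of the HP1c library and a different binding of HP1c on chromosome 4 stay open, no biological explanation was tested, and the pattern rests on 10 regions of 1 library.

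ROW regions covered fewer HP1c midpoints (21.5%) than positions 400 bp to the left (31.9%), though more than positions 3000 bp away (13.35%). An effect of the shared input that puts WOC, ROW and Z4 alike below their flanks at HP1c midpoints is argued against. Z4 coverage at the same midpoints was 1.88 times its coverage 400 bp away (bootstrap interval 1.78 to 1.99), and WOC coverage was 4.12 times. Whether this input affected the ROW calls alone, or lowered WOC and Z4 at the centre too without reversing them, cannot be told. The lists carry no score or read number. Short fragments in the ROW list were not needed for the dip. ROW regions of at least 200 bp alone covered 20.2% of HP1c midpoints and 29.7% of positions 400 bp to the left. Their ratio of centre to flank was 0.672 (0.629 to 0.7145). Narrower regions hold 6.30% of the whole ROW length, so this filter removed little of the list's coverage. That value does not give their share beside HP1c regions, so it does not show whether the ratio could have reached 1. With 1 ROW library, its fragment length and depth stay open, and neither they nor a biological explanation was tested.

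HP1c regions that overlap no region of another list made up 28.7% of the list. Narrow calls are argued against as the whole source. Of the narrowest 543 HP1c regions, 27.4% had no partner (exact interval 23.7 to 31.4%), against 40.4% of the 542 in the middle by width (36.2 to 44.7%). However, the widest 542 had the lowest share (10.5%, 8.06 to 13.4%). Width stood in for strength here, so calls near the threshold cannot be judged. Near misses of the overlap rule could underlie part of the pattern. Of these 777 regions, 64.7% lay within 500 bp of another list (13.55% under rotation, permutation p = 0.001, the smallest possible). The median gap of the 777 to another list was 241 bp, against their median width of 110 bp. ROW lay within 500 bp of 52.4%, Z4 of 32.6%, WOC of 22.4% and Dsk2 of 20.1%, and these shares were not compared with rotation list by list. Since ROW covered the flanks of HP1c midpoints more often than the midpoints, near misses and separate neighbouring regions cannot be told apart. The regions farther than 500 bp from any other list, of which 63 (8.11% of the 777) lay more than 10 kb away, are not covered by near misses, and no biological explanation was tested for them.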

How the results depend on the processing

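The 10 overlap shares stayed above rotation with a permutation p of 0.001 or less in all 90 alternative settings, at 4.62 to 74.8 times the rotated share. The contrasts between HP1c partners kept their direction and side of the threshold except in these cases, whose cause was not tested. When regions within 500 bp counted (chosen after seeing the data), Dsk2 minus WOC was 0, Dsk2 minus ROW and WOC minus ROW were both -1.84 percentage points, and ROW minus Z4 turned to 5.24 points (from -20.1). With the 50% widest regions of each list, ROW minus Z4 was -0.664 points. The number of merged regions with all 5 proteins (921) was 297 with the 50% widest regions, 371 with equal-length lists and 593 with regions of at least 50 bp, which hold fewer regions by construction, and 339 with every region set to 200 bp, which widens narrow regions and narrows wide ones. HP1c minus Z4 on chromosome 4 was -0.369 points with equal-length lists and no longer passed. Width differences by midpoint turned to -38 bp for HP1c with Z4, -65 bp for Z4 with HP1c and -21 bp for Z4 with ROW, all past the threshold, and to -6 bp for HP1c with WOC, which did not pass. No paired analysis was possible because each protein had 1 library, which also excluded leaving out replicates. Alternatives for start sites, genes, gene lists, promoters and motifs were not run, since regions were not assigned to genes, and width as a replacement for the score was already the ranking used. Without read numbers, absence from a list shows only that the signal did not pass an unstated threshold.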

Other observations

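Regions on the mitochondrial genome were listed for 3 of the proteins, with 3 for HP1c, 4 for Dsk2 and 4 for Z4, and none for WOC or ROW. HP1c, Dsk2 and Z4 regions lay close together at positions 4526 to 4559, 4520 to 4698 and 4504 to 4709, and again at 17257 to 17767, 17188 to 17498 and 17170 to 17495. Sequences outside the 5 large arms, chromosome 4 and the mitochondrial genome held 32 HP1c regions (1.18%), 82 Dsk2 regions (1.73%), 88 WOC regions (1.505%), 82 ROW regions (0.911%) and 108 Z4 regions (1.44%). The third widest region of WOC alone was of this kind, at 353 bp on the unplaced sequence Uextra (10241371 to 10241723).

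The share of HP1c regions with a partner was not steady across widths. It was highest for all 4 partners in the widest 542 HP1c regions, with 83.95% for Dsk2, 78.2% for WOC, 65.1% for Z4 and 47.6% for ROW. In the 542 in the middle by width the values were 51.3%, 48.0%, 39.1% and 22.5%, and in the narrowest 543 they were 58.4%, 55.2%, 48.4% and 19.5%.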
